A study of Mus musculus with 2 samples.

How the data were processed

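RNA was sequenced from brain neural stem cells of ICR mice at embryonic day 13, with 1 control and 1 knockdown library from total RNA on an Illumina instrument, per the labels. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 and the build mm9, and do not give their order or settings. The gene positions in the table are those of GRCm38: of 19595 gene IDs, 19557 were found in GENCODE M21, 19540 of them at an overlapping position and 18241 with the same start and end. Positions are printed as the table gives them. The libraries' strandedness is not stated in the labels.

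The authors deposited 1 table of 19595 genes, with a raw count per gene and library per the file headers. Its lowest sum over both libraries was 2 counts, 217 genes stood at 0 in the control and 356 in the knockdown library, and 15095 genes were protein-coding. The authors also deposited normalised values, which are CPM made from the counts with 1 factor per library, a count of 0 being replaced by 0.5. The deposited fold change is the ratio of these CPM, knockdown over control, and the deposited log2 column is its log2. The deposited p-value and adjusted p-value come with no named test, per the file headers. The adjusted value lies below the unadjusted p for 11417 genes, and its median quotient to a Benjamini-Hochberg adjustment of the same p-values is 0.417, with 94.2% of quotients within 0.001 of it. The authors' adjusted p-values were therefore not used for any count other than in the alternatives. Gene symbols that a spreadsheet had turned into dates (22) were restored from the gene ID, and 13 symbols stand for more than 1 gene.

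All other values were computed from the deposited counts. Libraries were scaled with edgeR's TMM factors (1.018 for the control, 0.982 for the knockdown library). The log2 fold is that of the count plus 0.5 over the scaled library, knockdown over control, and CPM and ratios are scaled counts without that addition. Genes with a mean of at least 1 CPM over both libraries were kept (14158). With 1 library per group no test across genes was made and no p-value was computed, and genes were counted by a fixed rule of 2-fold. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval, which covers counting error only, as do the floors of 3 counts used for genes at 0. Sequenced fragments copied by PCR are not independent molecules.

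The gene lists, the rule for named genes, the tests and the alternatives were chosen before the data were examined, unless stated otherwise. Named genes are Ccdc25, the 12 with the largest fold in each direction among genes with a mean of at least 10 CPM, and up to 4 members of each list by absolute log2 fold. Predicted genes, RIKEN clones and pseudogenes were left out of the 12. Single values of some list members that the rule takes are not given here. Each list is summarised by the median log2 fold of its members past the minimum, and by the percentile of that median among 10000 random lists of the same size drawn from the same 20 expression bins. The percentile describes these libraries and is not a p-value. The lists cover neural stem cells, intermediate progenitors, neurons, interneurons, astrocytes, oligodendrocytes, microglia and macrophages, endothelial cells and pericytes, mesenchyme, erythroid, ependymal and choroid plexus cells. They also cover S phase, G2 and M phase, histones, the Notch, Wnt, Sonic hedgehog and BMP/TGF-beta pathways, focal adhesion, extracellular matrix, p53 targets, apoptosis, interferon and inflammatory genes. The remaining lists are immediate early genes, stress responses, heat shock proteins, glycolysis, cholesterol synthesis, mitochondrial and ribosomal genes, axon guidance and synapse. Named genes that overlap another gene in GENCODE M21 were looked up for shared exonic bases. Some overlaps are given beside the gene, and other named genes also share exonic bases with another gene.

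The calculation was tested on simulated data, with Poisson counts for 1 control and 1 knockdown library of 19595 genes and 200 genes given known folds. Of the simulated 3-fold genes 99.0% passed 2-fold, of the 1.5-fold genes 2.0% did, and of 13988 unchanged genes 22 did. Both simulated libraries came from 1 shared expression profile and held counting error alone. These shares therefore do not tell how often unchanged genes pass 2-fold between separate cultures. The interval held 95.5% of the simulated ratios, and 6.0% of 1000 random lists lay in the outer 2.5% of either tail. The number of random lists was raised from 200 to 1000 after a first run gave a higher share.

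Alternatives were DESeq2's median-of-ratios factors, total-count scaling, the authors' CPM, no expression minimum, a minimum of 10 CPM, a prior count of 5 and a threshold of 1.5-fold. For the authors' calls they were an adjusted p below 0.01 and no fold threshold. A further alternative, the removal of the trend with transcript length and GC content, was added after the data were seen. It used GENCODE M21 values, found for 99.9% of genes past the minimum. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0, the last 2 for scaling factors alone.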

Results

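The series measured messenger RNA by sequencing in brain neural stem cells of ICR mice at embryonic day 13, in control cells and in cells with Ccdc25 knocked down. The title of the series asks how Ccdc25, a coiled-coil domain protein, bears on neurogenesis. The deposited table holds 1 control library, labelled psicor with the genotype WT, and 1 knockdown library, labelled sh1 with the genotype KO. The design text speaks of triplicates, and the table gives 1 column of counts per group, so no difference below has a replicate check and none was tested. The labels do not say whether a column stands for a single culture, a pool or a sum of replicates. Every comparison is between these 2 libraries, and each 95% interval of a ratio is an exact conditional binomial one that covers counting error only. The table assigned 16549682 counts to genes in the control library and 16058407 in the knockdown library. A floor of 3 counts corresponds to 0.178 CPM (counts scaled to a common library size) in the control and 0.19 CPM in the knockdown library.

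Ccdc25, the targeted gene, was lower in the knockdown library by 20.6% (95% counting interval 9.6% to 30.3%). Ccdc25 (ENSMUSG00000022035, chromosome 14, 65837302 to 65866607 on the plus strand in the GRCm38 positions of the table) had 553 counts in the control and 411 in the knockdown library. These counts correspond to 32.8 and 26.1 CPM and to a ratio of 0.794 (0.697 to 0.904), a log2 fold of -0.33. Among the 708 genes of like expression, 52.5% differed less between the libraries than Ccdc25 did, and 186 genes (26.3%) lay further below their control level. The direction is that of the labels, and the size is near the median absolute log2 fold of 0.314 in that group of genes.

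The medians of the glial and progenitor gene lists were higher in the knockdown library, and those of neurons, of interneurons and of dividing cells were lower. Gfap (ENSMUSG00000020932), the intermediate filament of astrocytes, stood at 3.09 CPM in the control and 481 CPM in the knockdown library, a ratio of 156 (119 to 209). Gpr17 (ENSMUSG00000052229), a receptor of immature oligodendrocytes, stood at 2.67 and 234 CPM, a ratio of 87.7 (65.4 to 120). In the opposite direction, Reln (ENSMUSG00000042453), the secreted guidance protein of Cajal-Retzius cells, stood at 45.0 and 2.85 CPM, a ratio of 0.0634 (0.0459 to 0.0857). Syt1 (ENSMUSG00000035864), the calcium sensor of synaptic vesicles, stood at 97.3 and 7.86 CPM, a ratio of 0.0808 (0.0668 to 0.0970).

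Of the 14158 genes with a mean of at least 1 CPM, 1082 were at least 2-fold higher in the knockdown library and 1098 at least 2-fold lower. The other 11978 genes (84.6%) lay within 2-fold. Protein-coding genes made up 887 of the higher and 989 of the lower genes. The counting interval excluded a ratio of 1 for 1074 of the higher genes and for all 1098 lower ones. The median log2 fold over all genes past the minimum was -0.004. Mitochondrially encoded genes took 4.03% of the counts in the control and 4.91% in the knockdown library.

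Among genes with a mean of at least 10 CPM, the 12 furthest above their control level were Gfap, Scrg1, Gpr17, Agt, Lims2, Rassf10, Padi2, Neurog2, Coq8a, Apoe, Ndrg2 and Myrf. Scrg1 had 3 counts in the control and 390 in the knockdown library, so its ratio of 139 carried a wide interval (47.2 to 677). Agt, which encodes angiotensinogen and is made by astrocytes, had a ratio of 52.2 (32.0 to 91.8). Neurog2, a proneural transcription factor, stood at 1.31 and 38.7 CPM, a ratio of 29.7 (19.4 to 47.7). Apoe, the main apolipoprotein of astrocytes, stood at 151 and 3484 CPM, and Ndrg2, also abundant in astrocytes, at 35.4 and 808 CPM. Myrf, a transcription factor of the myelin programme, had a log2 fold of 4.50, and Rassf10, Padi2 and Coq8a had 5.19, 5.12 and 4.64. Lims2 had a log2 fold of 5.45, but Gpr17 lies inside Lims2 on the opposite strand, with 188 exonic bases in common. Lims2 had 13 and 551 counts, beside 45 and 3693 for Gpr17. The labels do not say whether counting used strand, so the value for Lims2 is uncertain. Coq8a, with 15 counts in the control and 362 in the knockdown library, shares 366 exonic bases with Cdc42bpa on the opposite strand. Cdc42bpa had 1304 and 869 counts, so its reads would not account for the higher Coq8a count. The exact size of the Coq8a ratio stays uncertain if reads were counted without strand.

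The 12 genes furthest below their control level were Reln, Lrfn5, Syt1, Acta2, Sst, Ablim3, Rgs4, Gad2, Slc32a1, Vgf, Nefl and Ldb2. Sst, which encodes the interneuron peptide somatostatin, stood at 88.7 CPM in the control and 9.89 CPM in the knockdown library, a ratio of 0.112 (0.0940 to 0.132). Gad2, an enzyme of GABA synthesis, had a log2 fold of -3.02, and Slc32a1, the vesicular GABA transporter, -2.98. Acta2, the smooth muscle actin, stood at 261 and 22.8 CPM, a ratio of 0.0875 (0.0784 to 0.0975). Lrfn5, a synaptic adhesion protein, had a log2 fold of -3.69, Ablim3 -3.11, Rgs4 -3.06, the secreted neuropeptide precursor Vgf -2.92, Nefl -2.84 and Ldb2 -2.78. Nefl shares 1108 exonic bases with Nefm on the opposite strand and Slc32a1 shares 697 with an antisense gene, so both are uncertain if reads were counted without strand.

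**Figure D1:**
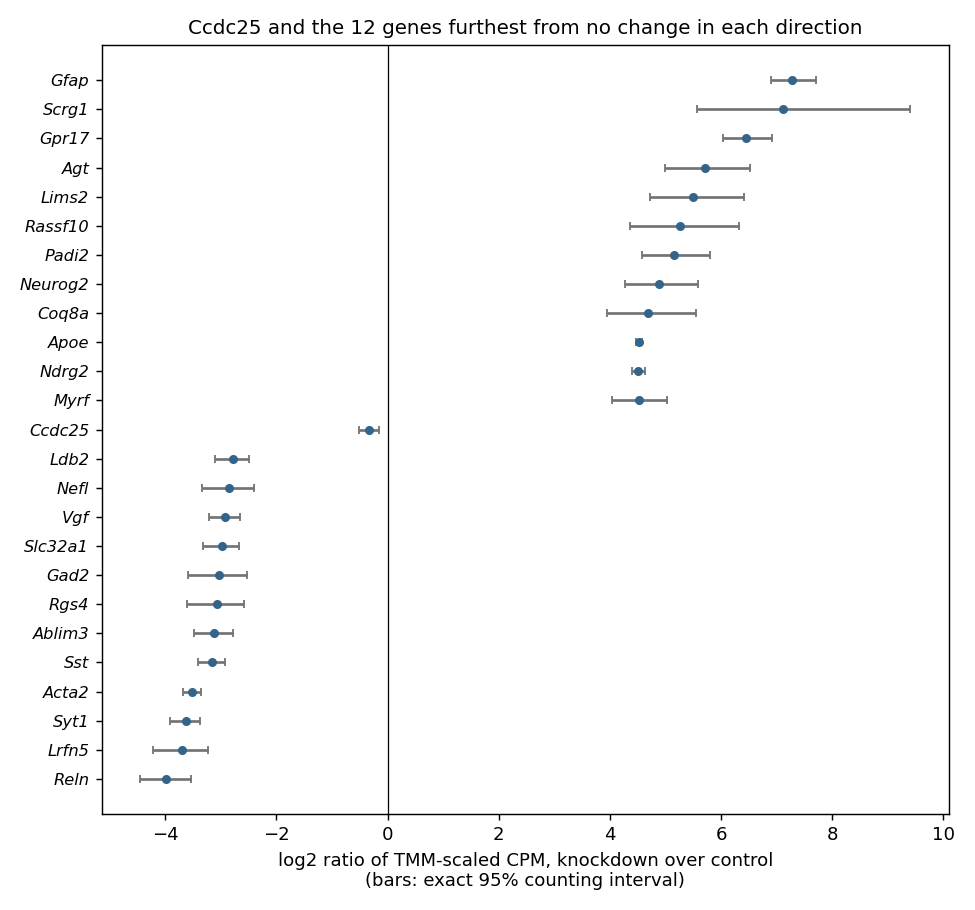
Log2 ratio of TMM-scaled CPM, knockdown over control library, for Ccdc25 and the 12 genes furthest from no change in each direction among genes with a mean of at least 10 CPM. Points are the ratios of 1 library per group and bars their exact 95% counting intervals; Ccdc25 at -0.33 lies close to 0 beside Gfap at 7.27 and Reln at -3.96.

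Of the 22 genes of neural stem cells and radial glia past the minimum, 5 were at least 2-fold higher in the knockdown library, 0 were 2-fold lower and 17 lay within 2-fold. The list's median log2 fold was 0.72, at percentile 100 among 10000 random lists matched on expression. Id4, an inhibitor of bHLH factors, stood at 26.5 and 108 CPM, a ratio of 4.07 (3.66 to 4.53). Hes5, a Notch effector, had a log2 fold of 1.73, Mt3 1.37 and Msi1 1.26. In all, 18 members were above and 4 below their control level, the latter being Hes1 at -0.73, Tnc at -0.71, Lix1 at -0.47 and Ccnd1 at -0.09, named after their values were seen. Among intermediate progenitor and proneural genes, 7 of 13 were at least 2-fold higher and 0 lower, with a median log2 fold of 1.09 at percentile 100. After Neurog2, the furthest were the cell cycle inhibitor Cdkn1c at a log2 fold of 2.39, Gadd45g at 2.05 and the Notch ligand Dll3 at 2.02. Cdkn1c shares 625 and Hes5 433 exonic bases with a gene on the opposite strand, so both are uncertain if reads were counted without strand. Of 18 Notch pathway genes, 7 were at least 2-fold higher and 1 lower, with a median log2 fold of 0.88 at percentile 100. Heyl had a log2 fold of 3.17 and the ligand Dll4 1.71, and 5 genes of the Notch list also belong to other lists.

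The neuronal, interneuron and synapse lists had medians below 0. Of 24 genes of newborn and differentiating neurons, 16 were at least 2-fold lower and 0 higher, with a median log2 fold of -1.66 at percentile 0. Tbr1, a transcription factor of early cortical neurons, stood at 74.2 and 16.9 CPM, a ratio of 0.228 (0.199 to 0.261), and Neurod6 had a log2 fold of -2.06. Of 13 genes of the ventral forebrain and interneuron lineage, 9 were at least 2-fold lower and 0 higher, with a median log2 fold of -2.60 at percentile 0. Dlx5, a homeodomain factor of this lineage, had a log2 fold of -2.97. Synapse genes were at least 2-fold lower in 11 of 21 cases and higher in 0, with a median log2 fold of -1.05 at percentile 0. Besides Syt1, the furthest were the glutamate transporter Slc17a6 at -2.50, the AMPA receptor subunit Gria1 at -2.14 and Snap25 at -1.95. Of 26 genes of axon guidance and cell adhesion, 7 were at least 2-fold lower and 1 higher, with a median log2 fold of -0.34 at percentile 0.28. Unc5d had a log2 fold of -2.48, L1cam -1.67, Sema3c -1.60 and the netrin receptor Dcc 1.44.

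The lists of both macroglial lineages had medians above 0. Of 12 astrocyte genes, 8 were at least 2-fold higher and 0 lower, with a median log2 fold of 1.19 at percentile 100. S100b had a log2 fold of 4.20, and the water channel Aqp4 stood at 5.58 and 61.4 CPM, a log2 fold of 3.45. Of 11 genes of the oligodendrocyte lineage, 8 were at least 2-fold higher and 0 lower, with a median log2 fold of 2.73 at percentile 100. The most abundant members, Olig1 and Olig2, were named after their values were seen and lay within 2-fold. Olig1 stood at 1751 CPM in the control and 2432 CPM in the knockdown library, and Olig2 at 1087 and 1401 CPM. The transcription factor Sox10 stood at 11.3 and 237 CPM, a log2 fold of 4.39. Mbp, a structural protein of myelin, stood at 7.66 and 99.7 CPM, a log2 fold of 3.70. Mog, a late myelin gene named after its value was seen, was the 1 member below its control level, with 24 and 11 counts and a ratio of 0.490 (0.217 to 1.04).

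Lists of other cell types that such cells could include were examined as well. With the expression minimum, only the mesenchyme list had a median outside the range of random lists. Of 12 genes of meningeal fibroblasts and mesenchyme, 7 were at least 2-fold lower and 2 higher, with a median log2 fold of -1.58 at percentile 0. Besides Acta2, the matrix genes Postn and Dcn had log2 folds of -3.60 and -2.76, while Pdgfra, which oligodendrocyte progenitors also express, had 2.94. Pdgfra shares 456 exonic bases with an antisense gene. Only 4 of 15 microglia and macrophage genes passed the minimum, with a median log2 fold of -0.65 at percentile 7.2. Without the expression minimum it was -3.48, and -1.63 with genes at 0 in a library placed at 3 counts. Of the genes past the minimum, Lyz2 had 309 counts in the control and 16 in the knockdown library, Aif1 had a log2 fold of -0.88 and Cd68 -0.41. The 4 endothelial and pericyte genes past the minimum had a median log2 fold of 0.45 at percentile 83.2, which was -0.41 without the expression minimum. Pdgfrb had a log2 fold of 2.16, Cspg4, also a gene of oligodendrocyte progenitors, 1.18, the endothelial receptor Kdr -1.33 and Egfl7 -0.27. The 3 ependymal and choroid plexus genes past the minimum lay within 2-fold, with a median log2 fold of -0.26 at percentile 25.9, which was 0.064 without the minimum. Foxj1 was at 0.86, Otx2 at -0.69 and Rsph1 at -0.26. Of the erythroid genes, 2 were listed and 0 passed the minimum.

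All 22 S phase genes past the minimum had log2 folds below 0, 20 of them within 2-fold and 2 beyond it, with a median log2 fold of -0.64 at percentile 0. The counting interval lay below a ratio of 1 for 21 of them, the exception being Orc1 at 0.887 (0.648 to 1.21). Tyms, an enzyme of thymidylate synthesis, stood at 71.4 and 29.7 CPM, a ratio of 0.415 (0.373 to 0.463). The licensing factor Cdc6 had a log2 fold of -1.10, Uhrf1 -0.94 and Ccne1 -0.88. All 24 genes of G2 and M phase had log2 folds below 0, 20 of them within 2-fold and 4 beyond it, with a median log2 fold of -0.82 at percentile 0. Anln, a scaffold of the cleavage furrow, had a log2 fold of -1.54, the checkpoint kinase Bub1 -1.06, the kinesin Cenpe -1.05 and Kif20a -1.15, though Kif20a shares 1271 exonic bases with Cdc23 on the opposite strand. Of the replication-dependent histone genes, 2 passed the minimum, Hist1h1c at a log2 fold of 1.31 and Hist1h2bc at -0.0070.

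The lists of immediate early genes and of sterol synthesis also had medians below 0. Of 15 immediate early genes, 9 were at least 2-fold lower and 0 higher, with a median log2 fold of -1.13 at percentile 0. Egr1 stood at 844 and 194 CPM, a ratio of 0.230 (0.221 to 0.239), Zfp36 had a log2 fold of -1.75, Fos -1.67 and Fosb -1.32. Of 18 cholesterol biosynthesis genes, 17 were lower, 4 of them at least 2-fold, with a median log2 fold of -0.75 at percentile 0. Msmo1, a sterol demethylating enzyme, had 3028 counts in the control and 1182 in the knockdown library, a ratio of 0.417 (0.390 to 0.446). Fdps had a log2 fold of -1.49 and shares 1124 exonic bases with another gene on its strand. Extracellular matrix genes had a median log2 fold of -0.63 at percentile 0, with 5 of 18 at least 2-fold lower and 1 higher. Lama1 had a log2 fold of -2.48, Thbs1 -2.01 and Fn1 -1.57, while Bcan, a proteoglycan of neural tissue, stood at 523 and 2298 CPM.

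The list of integrin-linked kinase and focal adhesion genes lay near 0, with a median log2 fold of -0.052 at percentile 31.4 and 18 of 20 genes within 2-fold. Its 2 exceptions were Lims2 and Parvb, which both encode partners of integrin-linked kinase. Parvb stood at 12.5 and 88.3 CPM, a ratio of 7.05 (6.09 to 8.19), and Pxn and Itgb3 had log2 folds of 0.96 and 0.78.

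The Wnt, Sonic hedgehog and BMP lists had medians inside the range of random lists. Wnt pathway genes had a median log2 fold of -0.064 at percentile 31.7, with 14 of 15 within 2-fold, and 0.085 without the expression minimum. Rnf43, a Wnt antagonist, had a log2 fold of 2.58, Nkd2 -0.93, Wnt7b 0.85 and Fzd7 0.77. Sonic hedgehog genes had a median of 0.12 at percentile 77.0, and Gli1, a target of the pathway, stood at 3.56 and 0.444 CPM, a ratio of 0.125 (0.0481 to 0.273). Ptch1 had a log2 fold of 0.66 and Mycn -0.75. BMP and TGF-beta genes had a median of 0.13 at percentile 81.2, with 3 of 18 at least 2-fold higher and 1 lower. The ligand Bmp4 stood at 0.771 and 12.9 CPM, a ratio of 16.8 (9.59 to 32.0), its receptor Bmpr1b had a log2 fold of 1.11 and Tgfb1 had -1.51.

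Most p53, apoptosis, stress response and heat shock genes lay within 2-fold. Of 19 p53 targets, 18 lay within 2-fold, with a median log2 fold of -0.15 at percentile 11.3, and Sesn1 was furthest at 1.03, with Plk2 at -0.74, Gtse1 at -0.69 and Trp53inp1 at 0.60. Of 17 apoptosis genes, 16 lay within 2-fold, with a median of -0.21 at percentile 6.5. Bcl2l11, a pro-apoptotic BH3 protein, had a log2 fold of 1.16, Casp8 -0.94 and Birc5 -0.67. Interferon genes had a median of 0.021 at percentile 54.0, which was -0.031 after scaling to total counts, and Ifih1, Rsad2, Mx2 and Ifitm3 had log2 folds of 1.37, -1.09, 1.01 and -0.77. Inflammatory genes, 5 of 10 within 2-fold, had a median of -0.12 at percentile 28.7, the same with Ccl3 placed at its bound and 1.01 among genes with a mean of at least 10 CPM. Ccl3 had 58 counts in the control and 0 in the knockdown library, at least 18.1-fold lower against a floor of 3 counts, while Vcam1 had a log2 fold of 1.59, Ptgs2 2.12 and Icam1 -1.46. Icam1 shares 511 exonic bases with an antisense gene. Genes of the unfolded protein and integrated stress responses had a median of -0.19 at percentile 5.24, with Chac1 at -2.09, Atf3 at -1.18, Trib3 at -1.03 and Ddit4 at 1.15. The 10 heat shock genes past the minimum were all lower and within 2-fold, with a median of -0.34 at percentile 1.58. Hspa1b had a log2 fold of -0.86, Hsp90aa1 -0.77, Hspd1 -0.55 and Hspa8 -0.45.

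Most metabolic, mitochondrial and ribosomal genes lay within 2-fold. Glycolysis and hypoxia genes had a median log2 fold of -0.16 at percentile 9.08, with the lactate transporter Slc16a3 at 1.93, Pdk1 at 0.80, Bnip3 at 0.66 and Pfkp at -1.72, though Pfkp shares 748 exonic bases with Pitrm1 on the opposite strand and Bnip3 504 with an antisense gene. The mitochondrially encoded genes had a median of 0.41 at percentile 98.8, all 12 within 2-fold, with mt-Nd5 at 0.72, mt-Nd4l at 0.65, mt-Nd3 at 0.63 and mt-Nd4 at 0.60. Cytosolic ribosomal protein genes had a median of 0.037 at percentile 61.8, which was -0.015 after scaling to total counts. Rps2 had a log2 fold of -1.12, Rpl13 0.36, Rps14 0.23 and Rplp1 -0.19, and ribosomal protein genes share reads with many processed pseudogenes.

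**Figure D2:**
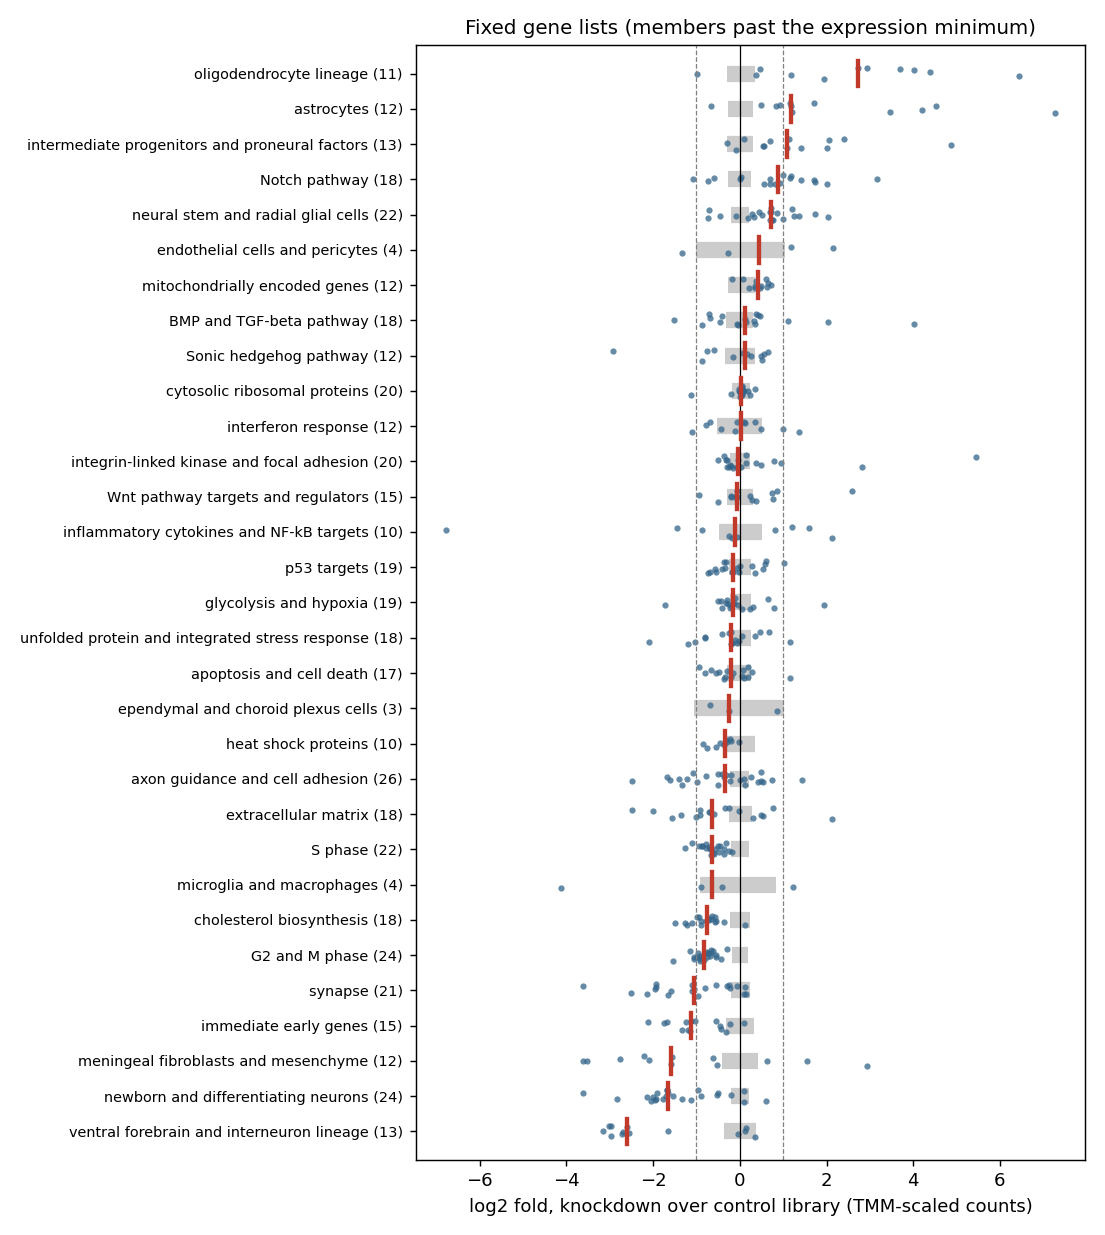
Log2 fold, knockdown over control library, for the members of each gene list past the minimum of 1 CPM (points; number in brackets), with the list median (red) and the central 95% of medians of 10000 expression-matched random lists (grey). Dashed lines mark 2-fold; the medians range from -2.60 for the ventral forebrain and interneuron lineage to 2.73 for the oligodendrocyte lineage.

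The authors' deposited table calls 1662 genes higher and 2003 lower in the knockdown library, 3665 in all. For all 19595 genes the calls equal those with an authors' p below 0.05 and an absolute log2 fold of at least 1. Of the called genes, 2097 were also at least 2-fold apart here, and 1463 had a mean under 1 CPM. The authors gave Ccdc25 a log2 fold of -0.38, p = 3.86e-05 and adjusted p = 5.12e-05, and did not call it. With 1 library per group these p-values compare the libraries, not the conditions. For the 19436 genes with a p above 1e-250, the authors' p equals, within 0.01 on the log10 scale, one computed from counting error alone.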

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

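The length and GC correction and the placing of genes at 0 at 3 counts were chosen after the data were seen. In all, 908 values were recomputed, of which 8 list medians and 1 named gene changed sign. With no filter the endothelial and pericyte median was -0.41, the ependymal and choroid plexus median 0.064 and the Wnt median 0.085. With total-count scaling and with the authors' CPM the ribosomal protein median was -0.015 in both, and the interferon median -0.031 and -0.032. The inflammatory median was 1.01 with at least 10 CPM, and Hist1h2bc was 0.078 after the length and GC correction. The microglia and macrophage median was -3.48 with no filter, and -1.63 with genes at 0 in a library placed at 3 counts. The counts of genes depend on the filter and the fold: 2286 higher and 2475 lower with no filter, 500 and 496 with at least 10 CPM, and 2259 and 2218 at 1.5-fold. The authors' adjusted p without a fold threshold is below 0.05 for 11534 genes. Total-count scaling and the authors' CPM gave medians of 0.664 in both for neural stem cells, -1.714 and -1.715 for neurons, 1.136 and 1.137 for astrocytes and -0.87 in both for G2 and M phase. With at least 10 CPM the medians were -2.11 for interneurons and 2.84 for oligodendrocytes. After the length and GC correction they were 1.11 for astrocytes, 2.61 for oligodendrocytes and -0.755 for G2 and M phase. Total-count scaling leaves out the TMM factors and so moves every log2 fold by the same amount. The authors' CPM imply library sizes of 16554034 for the control and 16061252 for the knockdown library, close to the total counts. The cause of the other shifts was not tested. Of 670 values of named genes 631 stayed within the counting interval and 39 lay outside it with the same sign. Of 213 list medians 177 stayed within the counting interval and 32 lay outside it with the same sign. The other scalings shifted the median of all genes to -0.020 (median-of-ratios), -0.057 (total counts) and -0.056 (the authors' CPM). No paired analysis was possible because there is 1 library per group, and leaving out a replicate, edgeR and DESeq2 tests and a replicate block were not run for the same reason. Depth limits genes near 0.178 and 0.19 CPM, the floors of 3 counts.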

Other observations

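The tests against length and GC bias, against a loss of neurons alone, against counting error in Ccdc25 and on macrophage genes were chosen after the results were seen, as were the Gene Ontology terms and the single genes named here outside the fixed lists. The tests of length and GC bias and of a loss of neurons replaced earlier versions, the first of which had left the question undecided. Among 881 Gene Ontology terms of 20 to 300 members, 145 had a median in the lowest 2.5% of 1000 random lists and 34 in the highest 2.5%, where unrelated terms would give 22 in each tail. Genes of GABA signalling were among the lowest, with a median log2 fold of -1.75 and 13 of 21 at least 2-fold lower in the knockdown library. Neuropeptide signalling had a median of -0.63 and initiation of DNA replication -0.67. Higher in the knockdown library were cell fate commitment, with a median of 0.60 and 11 of 39 genes at least 2-fold higher, and fatty acid beta-oxidation, with 0.57 over 35 genes. Positive regulation of neural precursor proliferation had 0.50 and lysosome organisation 0.34. Oligodendrocyte development had a median of 0.20 at percentile 97.8, with 8 of 23 genes at least 2-fold higher and 1 lower. The term for regulation of smoothened signalling had a median of 0.41 at percentile 99.8 and that for canonical Wnt signalling 0.20 at percentile 99.6, while the fixed Sonic hedgehog and Wnt lists lay inside the range of random lists.

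Several single genes of the oligodendrocyte lineage, picked after their values were seen and not tested as a group, stood far from their control level. Enpp6, a mark of newly formed oligodendrocytes, had 1 count in the control and 168 in the knockdown library, a ratio of 180 (31.8 to 7132). Fa2h, which makes hydroxylated myelin lipids, had 0 and 195 counts, at least 69.5-fold higher against a floor of 3 counts, and Mag had 3 and 134. Sirt2 was 4.36-fold, Pcdh15 7.99-fold, Cldn11 12.6-fold and C1ql1 20.8-fold higher. Of late myelin genes, Mobp had a ratio of 0.971 (0.370 to 2.52), Mal 1.47 (0.538 to 4.21) and Aspa 0.801 (0.229 to 2.63). Opalin had 5 and 0 counts, with an upper end of its ratio of 1.17. The counts of these genes were few, so a small difference was not detectable at this depth. Their intervals exclude a rise as large as that of Cldn11. Prss22 had 0 and 309 counts, Entpd2 0 and 291 and the neuronal bHLH gene Nhlh1 0 and 88, at least 110-fold, 104-fold and 31.3-fold higher. Entpd2 shares 612 exonic bases with Npdc1 on its strand. The predicted gene Gm10800, left out of the named genes by rule, had 754 counts in the control and 0 in the knockdown library.

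Higher glial and lower neuronal medians were weighed first. Gene length and GC bias is argued against, because the gap between the oligodendrocyte and neuron medians was 4.24 after the correction (resampling interval 2.04 to 5.69), near the uncorrected 4.39. A loss of neurons that raises every other cell type alike would raise the neural stem and mesenchyme medians alike. These medians differed by 2.29 (0.66 to 3.21). This pair was picked after both medians were known, so its outcome was known in advance and no conclusion is drawn from it. An effect of the knockdown itself stays open: with 1 library per group it cannot be told apart from any other difference between the 2 libraries, whose columns may each stand for a culture, a pool or a sum of replicates.

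The small difference in Ccdc25 was weighed next. Counting error is argued against, since the upper end of the interval of its ratio was 0.904 with TMM scaling. The ratio itself depended on the processing. It was 0.766 with total-count scaling and with the authors' CPM, and 0.861 after the length and GC correction. Within this pair of libraries 52.5% of genes of like expression differed less than Ccdc25. How far libraries of the same group differ is not measured with 1 library per group, so an ordinary difference between libraries and a weak knockdown of the transcript cannot be told apart. Protein levels are not analysed here.

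Macrophage genes made up the last pattern. Marco had 144 counts in the control and 0 in the knockdown library, Laptm5 136 and 1, Ctss 45 and 1, and Csf1r, which shares 873 exonic bases with Hmgxb3 on the opposite strand, 21 and 0. Low counts are argued against, because the summed counts of 11 listed markers, leaving out the 3 most abundant in the control, were 158 and 28, a ratio of 0.189 with an upper end of 0.284. Fewer macrophages among the knockdown cells may be a source, since 13 of 14 listed markers were lower, with Lyz2 the most abundant at 18.3 CPM in the control. Other cells also express some listed markers, such as Cd68, and 0 of them belong to another list. Whether the knockdown or the handling of the cells set their number cannot be told apart with 1 library per group.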
